A study of Mus musculus with 6 samples.

How the data were processed

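RNA from 3 ApoE KO and 3 wild type (WT) mouse aortas was measured on 2-colour Agilent arrays. Groups were taken from the genotype label of the Cy5 channel, which holds each aorta's own RNA, and replicate numbers from the sample titles. Per the labels' protocols, total RNA was extracted with Trizol and 100 ng was amplified in repeated rounds of reverse transcription and in vitro transcription, which can compress differences. Images were read with Agilent Feature Extraction 8.5.1.1, per the submitters' processing notes. The background correction, the dye normalization and any later software are not given in the sources used here.

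The deposited value table holds log10 ratios of own RNA over the common reference for 39556 probes. The authors' second deposited table gives the intensity of both channels, in arbitrary units after scaling by a method that is not given in the sources used here. Of its 18 columns of values per sample, 12 were not used, because the headings of 3 arrays name no group and the authors' p-values were not needed. The 3 arrays whose headings name C57BL6 were assigned to the WT group without a replicate number. For 100.0% of 39485 probes, the sorted 3 ratios of these arrays, computed as Intensity 2 over Intensity 1, equalled the sorted 3 WT values of the value table within 0.002 on the log10 scale. With the sign turned, 4.88% of the probes with a ratio away from 0 did so. This check fixed the scale and the direction for the WT arrays, and the ApoE KO arrays were taken to run the same way because their labels give the same dyes. The median log2 ratio was 0 on each of the 6 arrays, which exact zeros alone can give, so whether the ratios were centred remains unknown. Labels disagree in places: the Cy5 source names read db/+ at 9 weeks in both groups, and WT replicates 2 and 3 share a number there, but the values of these 2 arrays were not the same (SD of their difference 0.185 on the log2 scale). The unassigned array headings also speak of a vehicle and of 24 weeks of diet, so that genotype, age, diet length and vehicle may be confounded.

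Of the intensity values used, 99.99% were written to a step of 0.01, and the ratios had been formed from rounded values. As a result 36.2 to 58.9% of the ratios on an array were exactly 0, and 3788 features (10.8%) had the same value on all arrays. The reference intensity was under 0.1 for 13209 features. The SD of the log2 ratio was 0.259, 0.237 and 0.25 on ApoE KO replicates 1, 2 and 3 and 0.076, 0.091 and 0.136 on WT replicates 1, 2 and 3. No detection flags were used here.

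Log10 ratios were converted to log2. The 194 probes with a missing value were left out, which left 39362. Probes were named through a table of mouse RefSeq genes (assembly GRCm38.p6), 6984 by accession, 16552 by symbol and 2557 by synonym, while 3963 kept the name in the file and 9306 had none. For each of the 3568 symbols with over 1 probe, the probe with the highest level was kept. The level was the mean reference intensity of the 3 C57BL6-headed arrays times the mean of 1 and the average ratio over the 6 arrays. This gave 35027 features, 25721 of them with a symbol. Gene order near Apoe came from the same table, and no coordinates were used because the array's build is not given in the sources used here.

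Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with no trend, no block and no fold minimum, at a Benjamini-Hochberg adjusted p under 0.05 (two-sided). The prior degrees of freedom were 0.557 over all features and 3.42 over those with a level of at least 0.5, beside 4 residual ones. Lists of cell type markers and pathways, 29 in number, were tested with camera at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. Neither of fry's p values compares a list with other genes. Counts per list were made over all features and adjusted over the list alone. The genes named were Apoe, the 10 highest and the 10 lowest by log2 fold change among called genes with non-overlapping groups and a proper symbol, up to 3 members of each list in order of p, and members behind a count of 5 or fewer. Some genes that this rule names are not reported here. Design, lists, rule and most alternatives were fixed before the data were examined.

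The fit was tested on simulated arrays with the real levels, noise of bright features, rounding to 0.01 and 200 features with a level of at least 0.5 changed. Over all 35027 features it recovered 28% of changes of 1.25-fold, 68% of 1.5-fold, 92% of 2-fold and 98% of 4-fold, and 179 of 322 calls (55.6%) were false. Rounding leaves some dim features with a spread of 0, but whether this brought about the false calls was not tested. The share of false calls depends on the 200 features changed, so it does not carry over to the real calls. Over the 9034 features with a level of at least 0.5, where the rounding step is at most 2% of the level, it recovered 58, 94, 98 and 100%, with 5 of 180 calls (2.8%) false. This minimum was chosen after seeing the data, so the fit over all features was kept as the main one and the other is given beside it. A simulated list of 25 genes shifted by 0.3 was called, as was 1 of 100 unshifted lists. Genes were simulated independently of each other, so this does not test the preset correlation on lists of correlated genes.

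Alternatives were the replicate number as a block, centring on the mean of the central ratios of each array, quantile normalization between arrays, leaving out the dimmest features, the mean of a gene's probes, trend and robust eBayes, array weights, fold thresholds, and leaving out each array. Quantile normalization gives all arrays 1 distribution. The SD of the ratios before it was 0.237 to 0.259 on ApoE KO and 0.076 to 0.136 on WT arrays. It thereby narrows the ApoE KO ratios and widens the WT ratios, so calls lost after it may follow from the method. Chosen after seeing the data were the level minimum and lists without the neighbours of Apoe or without macrophage, foam cell and MHC class II members. Permutation and Fisher tests used scipy 1.17.1 with Python 3.11.15.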

Results

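The data were transcript ratios from 6 aortas of mice fed a high-fat diet, each hybridised to a 2-colour Agilent array. The 3 ApoE KO aortas came from mice that lack apolipoprotein E, the ligand by which remnant lipoproteins are cleared from plasma, and the 3 WT aortas came from C57BL6 mice. Per the labels, the knockout aortas carried atherosclerotic lesions and the wild type aortas had none. Each aorta's own RNA was labelled with Cy5 and set against a common Cy3 reference described as RNA of C57BL6 controls on a high-fat diet. Between 39480 and 39551 probes were measured per array, and the number of arrays limits the precision. The labels name biological replicates and do not say whether any aortas were pooled. The knockout mice were labelled 32 weeks old and the wild type mice 24 weeks, whereas the protocol gives both groups 16 weeks of diet from an age of 8 weeks, and the headings of arrays not assigned to a group speak of a vehicle and of 24 weeks of diet. Whether diet length and vehicle were the same in both groups is therefore not settled, and genotype, age, diet length and vehicle cannot be told apart in the comparison below. All fold changes are ApoE KO over WT on the log2 scale, with the standard error of the fit and n = 3 per group.

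Apoe, the targeted gene, was lower in the knockout aortas by 2.31-fold, with a log2 fold change of -1.21 ± 0.13 (SE) and an adjusted p of 0.00649 in limma. Its log2 ratio to the reference was -1.31, -1.21 and -1.31 in the knockout arrays and 0.00, -0.32 and 0.12 in the wild type arrays. The direction follows the labels of the samples. The probe was made for the transcript NM_009696, and whether it lies inside the deleted part of the gene is not given in the sources used here, so its remaining signal does not measure the knockout.

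The comparison of genotypes asked which transcripts differ between aortas of ApoE KO and wild type mice fed a high-fat diet. Of the 10 highest genes, Mmp12, Ctss, Atp6v0d2 and Mpeg1 belonged to the lists of macrophage markers, foam cell and lysosomal genes or matrix proteases. Mmp12, the macrophage elastase, was 10.2-fold higher (log2 fold change 3.35 ± 0.055), and Ctss, the lysosomal cysteine protease cathepsin S, was 9.25-fold higher (3.21 ± 0.08). Atp6v0d2, a subunit of the proton pump of lysosomes and osteoclasts, rose by 3.06 ± 0.065 on the log2 scale, and Mpeg1, a pore-forming protein of macrophages, by 3.00 ± 0.10. The decreases were smaller, and the lowest were Bcam, a laminin receptor of the immunoglobulin family, at 2.37-fold lower (-1.24 ± 0.085) and Mrps12, a protein of the mitochondrial ribosome, at 2.35-fold lower (-1.23 ± 0.04).

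Among the 10 highest genes were also Bex1 with a log2 fold change of 3.16, Lilrb4a, an inhibitory receptor of myeloid cells, with 3.01, and Il7r, the receptor chain for interleukin 7, with 2.88. Bcl2a1b, an anti-apoptotic gene with near-identical copies in the genome, so that its value is uncertain as that of 1 gene, Il1rn, the interleukin 1 receptor antagonist, and Rnf128, a ubiquitin ligase, followed with 2.85, 2.84 and 2.81. Adjusted p values of these 10 genes lay between 0.000179 for Mmp12 and 0.00182 for Il7r. Among the 10 lowest genes were, besides Bcam, Mrps12 and Apoe, the vomeronasal receptor gene Vmn2r29 (-1.14), the zinc finger genes Zfp74 (-0.98) and Zfp111 (-0.97), the sodium-proton exchanger Slc9a2 (-0.93), Rhobtb1 (-0.92) and the myosin light chain kinase family member Mylk4 (-0.88). The level of Zfp111 was 0.0889, below the median reference intensity of 0.143 over all features, and that of Vmn2r29 was 0.234. Each of the 20 genes had all knockout values on 1 side of all wild type values, and the call of Zfp111 was lost after quantile normalization (adjusted p 0.11) and without ApoE KO replicate 1 (0.0505) or 3 (0.053).

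**Figure D1:**
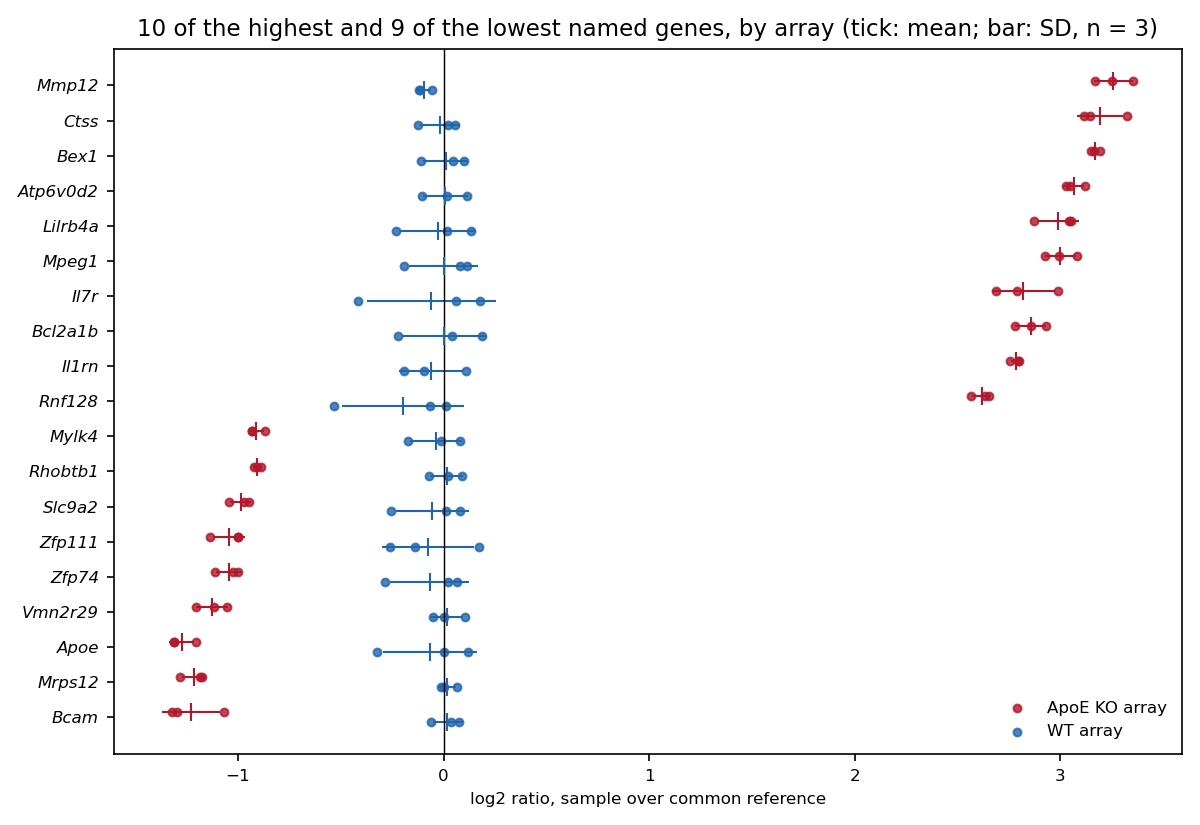
Log2 ratio of each array's own RNA over the common reference (horizontal axis) for the 10 highest and 9 of the 10 lowest named genes (vertical axis), with 3 ApoE KO arrays in red, 3 WT arrays in blue, ticks at means and bars for SDs of 3 arrays. Mmp12 lay highest at 3.35 above WT and Bcam lowest at -1.24, and no knockout value overlapped a wild type value.

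In all, 5158 of 35027 features (14.7%) changed at an adjusted p under 0.05 in limma, 2357 higher and 2801 lower in the knockout. Increases were larger than decreases: 369 genes rose and 4 fell by at least 2-fold, and 56 rose and 0 fell by at least 4-fold. The median log2 fold change was 0.43 among genes called higher and -0.21 among those called lower. Every called feature had non-overlapping groups, as did 29.3% of all features, where chance gives 10%. The balance turned with the scaling, to 2773 higher and 2394 lower after centring each array on the mean of its middle values and to 871 and 780, 1651 in all, after quantile normalization between arrays. Quantile normalization forces the wider ApoE KO ratios and the narrower WT ratios to 1 distribution. A call lost after it, here and below, may therefore be a result of the method. Lower calls numbered 1803 without ApoE KO replicate 3 and 1798 without WT replicate 2. Rounding of dim intensities limits the count over all features. Of the called genes named here, Ddx58, Lep, Adamts15, Abcg8, Cd28, Fmod, Ciart and Tgfb1 differed between groups by 0.8 to 2.9 rounding steps of 0.01 in intensity, so that their size is not resolved. The 3 WT log2 ratios were all exactly 0 for Ddx58, Lep, Adamts15, Abcg8, Cd28, Bhlhe41, Lcn2, Nppa, Clptm1, Mfap5, Myc, Msr1 and Loxl2, whose p values therefore rest in part on rounding. In simulated arrays, 179 of 322 calls in a fit over all 35027 features were false. When the fit was restricted to the 9034 features with a level of at least 0.5, 5 of 180 were false. On the real arrays, the restricted fit called 3924 features (1712 higher, 2212 lower), and 2669 of them were also called over all features. The median log2 ratio of these 9034 features was -0.051, -0.046 and -0.051 on ApoE KO replicates 1, 2 and 3. On WT replicates 1, 2 and 3 it was 0, 0 and -0.014. The larger number of lower calls there may follow from this offset, and no restricted fit was run without it.

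Macrophage and foam cell genes had the highest medians among the 29 gene lists. Of 30 macrophage markers, 24 rose and 0 fell, and 26 were higher and 2 lower when adjusted over the list alone. Their median log2 fold change was 1.40, which is 2.63-fold. Examples were Ctss (3.21), Lgmn (1.42), a lysosomal endopeptidase, and the scavenger receptor gene Msr1, which had a log2 ratio of 1.1 on each knockout array and 0 on each wild type array, an SD of 0 that rounding gave on a probe with a level of 0.0857. The 6 that did not pass included Cd68 (0.15), Cx3cr1 (-0.21) and Itgam (-0.29), named after their values were seen. At a level of at least 0.5 these passed (adjusted p 0.0303, 0.0205 and 0.0248), as did Cd68 with centring (0.0389), with array weights (0.0312) and without the dimmest features (0.044). Foam cell and lysosomal genes rose in 29 of 33 members with a median of 1.27, and 31 were higher when adjusted over the list alone. Mmp12 (3.35), Atp6v0d2 (3.06) and Fabp5 (2.13), a fatty acid binding protein of lipid-laden macrophages, had the lowest p values in that list. The camera test with a preset correlation gave adjusted p values of 1.08e-23 for macrophage markers and 1.43e-32 for foam cell genes. With an estimated correlation the adjusted p was 0.097 for each of these lists.

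**Figure D2:**
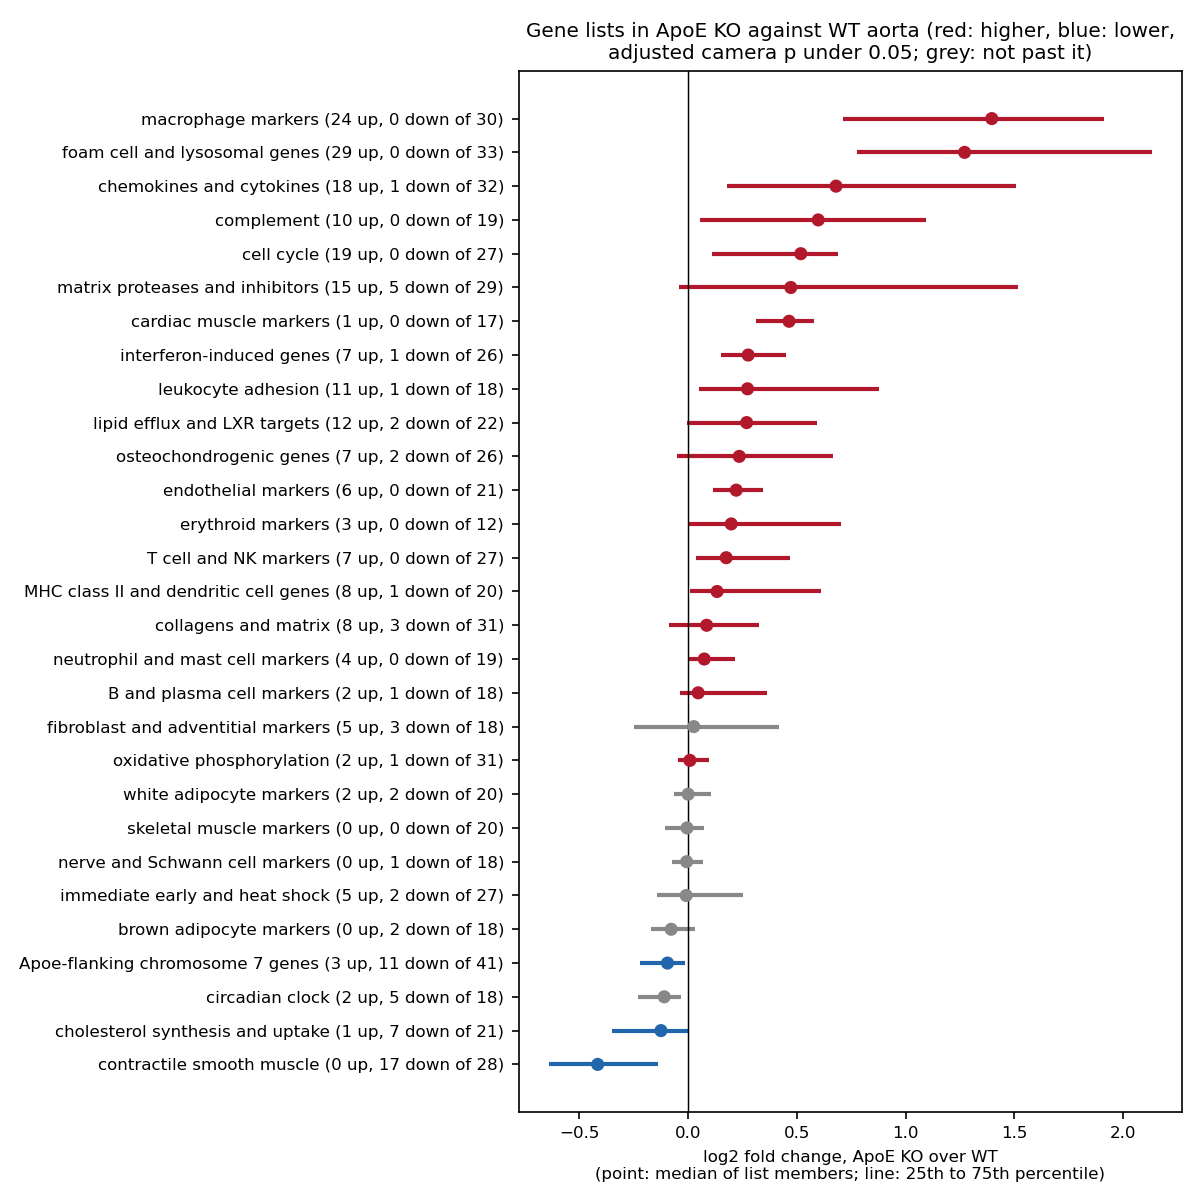
Median log2 fold change of ApoE KO over WT (horizontal axis, points) with the 25th to 75th percentile of members (lines) for the 29 gene lists (vertical axis), each with its number of members called higher and lower, in red and blue where camera with a preset correlation called the list higher and lower and in grey elsewhere. Macrophage markers lay highest at 1.40 and contractile smooth muscle genes lowest at -0.42.

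Chemokines, complement and adhesion genes were higher in the knockout aortas. Of 32 chemokines and cytokines, 18 were higher and 1 lower (22 and 2 when adjusted over the list alone), with a median log2 fold change of 0.68. Il1rn (2.84), Il6 (2.44) and Ccl2 (1.84), the main chemokine of monocytes, were the examples of lowest p, and Tgfb1 was the gene that fell (-0.17). Complement genes rose in 10 of 19 members and fell in 0 (12 and 1 adjusted over the list alone), with C1qc at 2.19, C1qb at 1.97 and the protease C1ra at 0.64. The complement median was 0.60, and it was 0.28 without members of the macrophage, foam cell and MHC class II lists, the first of which holds the C1q chains. Leukocyte adhesion genes were higher in 11 and lower in 1 of 18 members (12 and 2 adjusted over the list alone). In this list Itgax, an integrin of macrophages and dendritic cells, rose by 2.57, the endothelial selectin Sele by 2.35 and Cd44 by 1.07, and Jam3, a junctional adhesion molecule, fell (-0.45). The calls of Tgfb1 and Jam3 were lost after quantile normalization (adjusted p 0.473 and 0.171) and without 3 and 5 of the 6 arrays in turn (up to 0.0611 and 0.113). Camera with the preset correlation gave adjusted p values of 7.69e-13, 1.94e-07 and 4.47e-08 for chemokines, complement and adhesion. With an estimated correlation these adjusted p values were 0.104, 0.168 and 0.097.

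MHC class II and dendritic cell genes rose in 8 of 20 members and fell in 1 (10 and 1 adjusted over the list alone), and the median was 0.13. The costimulatory molecules Cd80 (1.31), Cd86 (1.28) and Cd83 (1.31) had the lowest p values in the list, and the dendritic cell lectin Cd209a was the member that fell (-0.24). Interferon-induced genes had a median of 0.28, with 7 higher and 1 lower of 26 (14 and 1 adjusted over the list alone). Ifih1 (0.58) and Bst2 (0.56) rose, and Ddx58, a sensor of viral RNA, fell by 0.094 on a probe with a level of 0.128. The calls of Bst2 and Cd209a were lost without 4 and 5 of the 6 arrays left out in turn (adjusted p up to 0.0785 and 0.16), and that of Cd209a with centring (0.0514), with the mean of a gene's probes (0.0509) and with trend and robust eBayes (0.06). After quantile normalization the calls of Cd86, Ifih1, Bst2 and Cd209a were lost (adjusted p 0.0862, 0.06, 0.208 and 0.163). Adjusted p values were 3.86e-05 for MHC class II and 6.38e-07 for interferon-induced genes with the preset correlation. The adjusted p was 0.142 and 0.272, in that order, with an estimated correlation, and for interferon-induced genes it was 0.0778 on features with a level of at least 0.5.

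The lists of lymphocyte and granulocyte markers had medians between 0.05 and 0.18. T cell and NK markers rose in 7 of 27 members and fell in 0 (9 and 0 adjusted over the list alone), and the examples were Il7r (2.88), Cd5 (0.83) and, on a probe with a level of 0.0815, Cd28 (0.33). Genes of the T cell receptor complex, its coreceptors and kinases did not pass: Cd8a was at 0.15, Cd3e at 0.05, Cd4 at 0.05, Lck at 0.03, Zap70 at -0.06 and Cd3d at -0.12, named after their values were seen, and Lck passed at -0.053 without ApoE KO replicate 2 (adjusted p 0.00342) and Cd8a without ApoE KO replicate 3 (0.0214). Among 18 B and plasma cell markers 2 rose and 1 fell (2 and 1 adjusted over the list alone): Cd22 by 2.21 and Tnfrsf13b by 0.45, while Pax5 was lower by a log2 fold change of -0.14. Neutrophil and mast cell markers rose in 4 of 19 members (4 adjusted over the list alone), namely Cxcr2 (0.95), Lcn2 (0.22), S100a8 (1.14) and S100a9 (1.17), and 0 fell. The adjusted p values were 2.57e-06 for T cell, 0.0489 for B cell and 0.0126 for neutrophil lists with the preset correlation. An estimated correlation gave an adjusted p of 0.168, 0.328 and 0.27. The B cell list lost its call without ApoE KO replicate 2 (adjusted p 0.2) or 3 (0.0584) and without WT replicate 1 (0.0595) or 2 (0.115), and also with centring (0.0798), quantile normalization (0.0706) and array weights (0.0567) and without the dimmest features (0.116). Single calls were lost without 5 of the 6 arrays in turn for Pax5 (adjusted p up to 0.104), 4 for S100a8 (0.0694) and S100a9 (0.101) and 2 for Lcn2 (0.052), and after quantile normalization for Pax5 (0.603), Cxcr2 (0.229), S100a8 (0.242) and S100a9 (0.36).

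The contractile apparatus of smooth muscle was lower in the knockout aortas. Of 28 contractile smooth muscle genes, 17 fell and 0 rose (20 and 0 adjusted over the list alone), with a median log2 fold change of -0.42. Lmod1 (-0.72 ± 0.051), an actin nucleator, Cnn1 (-0.73 ± 0.055), the calponin of smooth muscle, and Filip1l (-0.58 ± 0.046) had the lowest p values, and the alpha actin Acta2 (-0.68) and myosin heavy chain Myh11 (-0.61), whose adjusted p was 0.0524 after quantile normalization, were named after their values were seen. Among the 11 members that did not pass were Tpm1 (0.51), Pln (0.38) and Casq2 (-0.03), which heart muscle also expresses. They were picked after their values were seen. Tpm1 was at log2 ratios of -0.50, 0.38 and 0.61 in ApoE KO replicates 1, 2 and 3, where cardiac markers had medians of -0.58, 0.38 and 0.72. With 1 array left out in turn, Tpm1 ran from 0.142 to 0.837 and Pln from 0.041 to 0.799. Casq2 moved less, from -0.059 to 0.039, and whether heart tissue accounts for these members was not tested. The adjusted p was 4.85e-08 with the preset correlation and 0.103 with an estimated correlation.

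Endothelial markers rose in 6 of 21 members and fell in 0 (11 and 0 adjusted over the list alone), with a median of 0.22 and Sox17 (0.53), Vwf (0.47) and Esam (0.18) as examples. The calls of Vwf and Esam were lost without 3 and 4 of the 6 arrays in turn (adjusted p up to 0.0649 and 0.0757). Fibroblast and adventitial markers rose in 5 and fell in 3 of 18 (5 and 4 adjusted over the list alone), with a median of 0.03. Lum, a small proteoglycan, rose by 1.76, Has1, a hyaluronan synthase, by 0.66, Fbln2 by 0.66, Ly6a by 0.65 and Col14a1 by 0.34, and Ogn (-0.63), Serpinf1 (-0.46) and Mfap5 (-0.17) fell. Collagen and matrix genes rose in 8 and fell in 3 of 31 (13 and 3 adjusted over the list alone), with a median of 0.09, among them Col8a1 (1.66) and Loxl2 (0.33) upward and Col18a1 (-0.54), the laminin chain Lama4 (-0.53) and Loxl1 (-0.26) downward. Osteochondrogenic genes rose in 7 and fell in 2 of 26 (9 and 3 adjusted over the list alone), with a median of 0.24. The bone sialoprotein gene Ibsp rose by 2.49, the osteoprotegerin gene Tnfrsf11b by 1.55 and Hapln1 by 0.54, and Fmod (-0.12) and Sp7 (-0.11) fell. After quantile normalization the calls of Sox17, Vwf, Esam, Has1, Fbln2, Ly6a, Col14a1, Serpinf1, Mfap5, Loxl1, Tnfrsf11b, Hapln1, Fmod and Sp7 were lost, with an adjusted p between 0.0526 for Sox17 and 0.716 for Fmod. Leaving out arrays in turn ended the calls of Sp7 in 6 fits (adjusted p up to 0.133), of Fmod in 5 (0.132), of Ly6a, Col14a1 and Serpinf1 in 4 each (0.099, 0.0954 and 0.121), of Fbln2 and Loxl1 in 3 each (0.0571 and 0.0754) and of Mfap5 without WT replicate 2 (0.0513). The mean of a gene's probes ended those of Col14a1 (0.142) and Fbln2 (0.362), centring those of Fmod (0.075) and Sp7 (0.084), and trend and robust eBayes (0.055) or a level of at least 0.5 (0.0586) that of Sp7. The 4 lists had adjusted p values of 5.79e-06, 0.328, 0.00258 and 0.000471 with the preset correlation. With an estimated correlation the adjusted p was 0.27, 0.744, 0.272 and 0.142.

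Matrix proteases and their inhibitors changed in both directions. Of 29 members 15 rose and 5 fell (16 and 6 adjusted over the list alone), and the median was 0.47. Mmp12 and Ctss led, with Adam8, a membrane protease of myeloid cells, at 2.21 ± 0.034. The 5 that fell were Adamts1 (-0.50), Adamts8 (-0.44), Mmp23 (-0.25), Adamts5 (-0.19) and Adamts15 (-0.11), and Adamts4 of the same list rose by 0.80. After quantile normalization the calls of all 5 that fell were lost (adjusted p 0.206, 0.192, 0.301, 0.169 and 0.179). Without 5 of the 6 arrays in turn that of Adamts1 was lost (up to 0.144), without 4 those of Adamts8 (0.0833) and Adamts15 (0.112) and without 3 that of Mmp23 (0.0738), as were that of Adamts15 with centring (0.0571) and that of Adamts1 with trend and robust eBayes (0.0508). Without members of the macrophage, foam cell and MHC class II lists the median was 0.13. The adjusted p was 7.87e-08 with the preset correlation and 0.097 with an estimated correlation.

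In the list of lipid efflux genes and targets of the sterol receptor LXR, 12 of 22 members rose and 2 fell, Acat1 (-0.26) and Abcg8 (-0.18). Acat1 was counted because the list as fixed held it, and its fall is not read as one of efflux or LXR genes. When adjusted over the list alone, 13 were higher and 3 lower. Abcg1, a cholesterol exporter, rose by 2.71 ± 0.053, Ch25h, which makes 25-hydroxycholesterol, by 1.67 ± 0.077 and the lipase Lpl by 1.63 ± 0.069. Genes of cholesterol synthesis and uptake fell in 7 and rose in 1 of 21 (11 and 1 adjusted over the list alone), with Sqle, the squalene epoxidase, at -0.66 ± 0.028 and the regulator Srebf2 at -0.57 ± 0.064. Dhcr7 was the member that rose (0.26). After quantile normalization the calls of Acat1, Abcg8, Srebf2 and Dhcr7 were lost (adjusted p 0.381, 0.171, 0.109 and 0.336), and those of Acat1, Abcg8 and Dhcr7 were lost without 6, 5 and 5 of the 6 arrays in turn (up to 0.103, 0.0971 and 0.147), that of Dhcr7 also with trend and robust eBayes (0.054). Median log2 fold changes were 0.27 for efflux and -0.13 for synthesis, and the efflux median was 0.25 without macrophage, foam cell and MHC class II members. The adjusted p was 2.48e-06 for efflux and 0.0125 for synthesis with the preset correlation, and 0.176 for both with an estimated correlation.

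Cell cycle genes rose in 19 of 27 members and fell in 0 (21 and 0 adjusted over the list alone), with a median of 0.52. Examples were the centromeric histone Cenpa (0.59), the cyclin Ccna2 (0.70) and the replication helicase subunit Mcm3 (0.46). The adjusted p was 5.91e-14 with the preset correlation and 0.103 with an estimated correlation. Circadian clock genes rose in 2 and fell in 5 of 18 (2 and 6 adjusted over the list alone), with a median of -0.11: Bhlhe40 (1.19) and Bhlhe41 (0.31) rose, and Hlf (-0.68), Cry2 (-0.41), Nr1d1 (-0.38), Per2 (-0.33) and Ciart (-0.08) fell. The calls of Nr1d1, Per2 and Ciart were lost without 6, 5 and 5 of the 6 arrays in turn (adjusted p up to 0.126, 0.123 and 0.0668), and those of Cry2, Nr1d1, Per2 and Ciart after quantile normalization (0.158, 0.278, 0.221 and 0.62), that of Ciart with centring (0.063) and that of Nr1d1 with trend and robust eBayes (0.0575). The list had an adjusted p of 0.125, and of 0.0381 without WT replicate 3.

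Immediate early and heat shock genes rose in 5 and fell in 2 of 27 (7 and 3 adjusted over the list alone), with Junb (1.04), Egr2 (1.03), Atf3 (0.60), Klf4 (0.45) and Myc (0.44) higher and Jund (-0.39) and Hspb1 (-0.27) lower. After quantile normalization each of these calls but those of Egr2 and Myc was lost (adjusted p 0.62 for Junb, 0.16 for Atf3, 0.592 for Klf4, 0.336 for Jund and 0.264 for Hspb1). Leaving out arrays in turn ended the calls of Junb and Atf3 in 2 fits each (adjusted p up to 0.0518 and 0.0516), of Klf4 in 5 (0.151) and of Jund and Hspb1 in 6 each (0.154 and 0.155). Trend and robust eBayes ended those of Klf4, Jund and Hspb1 (0.0558, 0.0549 and 0.0594), and that of Hspb1 was lost with centring and with the mean of a gene's probes (0.0502 each). That list had an adjusted p of 0.102, and of 0.0336 without WT replicate 1, and its median of -0.01 differed in sign from its mean of 0.09 and from camera, which pointed to higher.

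Oxidative phosphorylation genes had a median of 0.01, and 3 of 31 passed the test, with Cox5a (0.39) and Ndufa1 (0.19) higher and Sdhc (-0.20) lower. When adjusted over the list alone, 2 were higher and 1 lower. The calls of Cox5a, Ndufa1 and Sdhc were lost without 5, 6 and 4 of the 6 arrays in turn (adjusted p up to 0.099, 0.0919 and 0.0935) and after quantile normalization (0.62, 0.916 and 0.166). The list's adjusted p was 0.0489 with the preset correlation and 0.596 with an estimated correlation. It was 0.197 without ApoE KO replicate 2, 0.196 without ApoE KO replicate 3, where the median was -0.01, 0.119 without WT replicate 2 and 0.162 at a level of at least 0.5. The call was also lost with centring (adjusted p 0.13), with the mean of a gene's probes (0.0758) and with array weights (0.0567).

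Markers of tissues that surround the aorta were measured as well. White adipocyte markers rose in 2 (Pparg 0.27, Mest 0.73) and fell in 2 (Acvr1c -0.16, and Lep -0.14 on a probe with a level of 0.0945) of 20 members, with a median of 0.00 and an adjusted p of 0.367, camera pointing to higher and fry to lower. Brown adipocyte markers fell in 2 of 18, Prdm16 (-0.52) and Dio2 (-0.52), while Pdk4 was at -0.33 with an adjusted p of 0.177, 0.0338 at a level of at least 0.5, and the list had a median of -0.08 and an adjusted p of 0.367. The calls of Pparg and Dio2 were each lost without 4 of the 6 arrays in turn (adjusted p up to 0.0891 and 0.0746), and that of Mest without 5 (0.137). After quantile normalization the calls of Pparg, Mest, Acvr1c and Dio2 were lost (adjusted p 0.143, 0.161, 0.121 and 0.185), and with the mean of a gene's probes those of Pparg, Mest and Acvr1c (0.606, 0.0618 and 0.733), that of Mest also with trend and robust eBayes (0.056). When adjusted over the list alone, the counts were again 2 and 2 for white and 0 and 2 for brown adipocytes. Of 20 skeletal muscle markers 0 passed, over all genes or adjusted over the list alone, and Tnni2 (0.57), Myl1 (0.28) and Atp2a1 (-0.14) had the lowest p. Tnni2 passed without the dimmest features (adjusted p 0.0456), with array weights (0.0124) and without WT replicate 3 (0.00733). That list had an adjusted p of 0.721. Nerve and Schwann cell markers had 1 of 18 lower, Sox10 (-0.17, 1 also adjusted over the list alone), with Cnp at 0.098, and the call was lost without 4 of the 6 arrays in turn (adjusted p up to 0.0852) and after quantile normalization (0.35). Their adjusted p was 0.721 too, with a median of -0.01 although camera pointed to higher. For the skeletal muscle list, the median of -0.01 and the mean of 0.06 also differed in sign. Erythroid markers rose in 3 of 12 (4 adjusted over the list alone), among them the globin genes Hbb-b2 (0.92) and Hba-a1 (0.63), with a median of 0.20, an adjusted p of 0.00335 and an adjusted p of 0.295 with an estimated correlation. The calls of both globin genes were lost without 5 of the 6 arrays in turn (adjusted p up to 0.144 and 0.143) and with trend and robust eBayes (0.0572 and 0.0513), that of Hbb-b2 after quantile normalization (0.576) and that of Hba-a1 with the mean of a gene's probes (0.0567).

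Cardiac muscle markers differed between arrays of the same group. Their median log2 ratio to the reference was -0.58, 0.38 and 0.72 in ApoE KO replicates 1, 2 and 3, and 0.00, -0.71 and 0.00 in WT replicates 1, 2 and 3. Of 17 members 1 rose, Nppa (0.46), 0 when adjusted over the list alone, a call lost without 5 of the 6 arrays in turn (adjusted p up to 0.141), after quantile normalization (0.105), with the mean of a gene's probes (0.0501) and with trend and robust eBayes (0.0594), and Myl7 (0.79 ± 0.50) and Myl4 (0.70 ± 0.37) did not pass the test. The list had an adjusted p of 0.0225 with the preset correlation and 0.617 with an estimated correlation. Its call was lost without ApoE KO replicate 2 (adjusted p 0.0957), without ApoE KO replicate 3 (0.196) and without WT replicate 2 (0.175), with centring (0.136) and at a level of at least 0.5 (0.126).

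**Figure D3:**
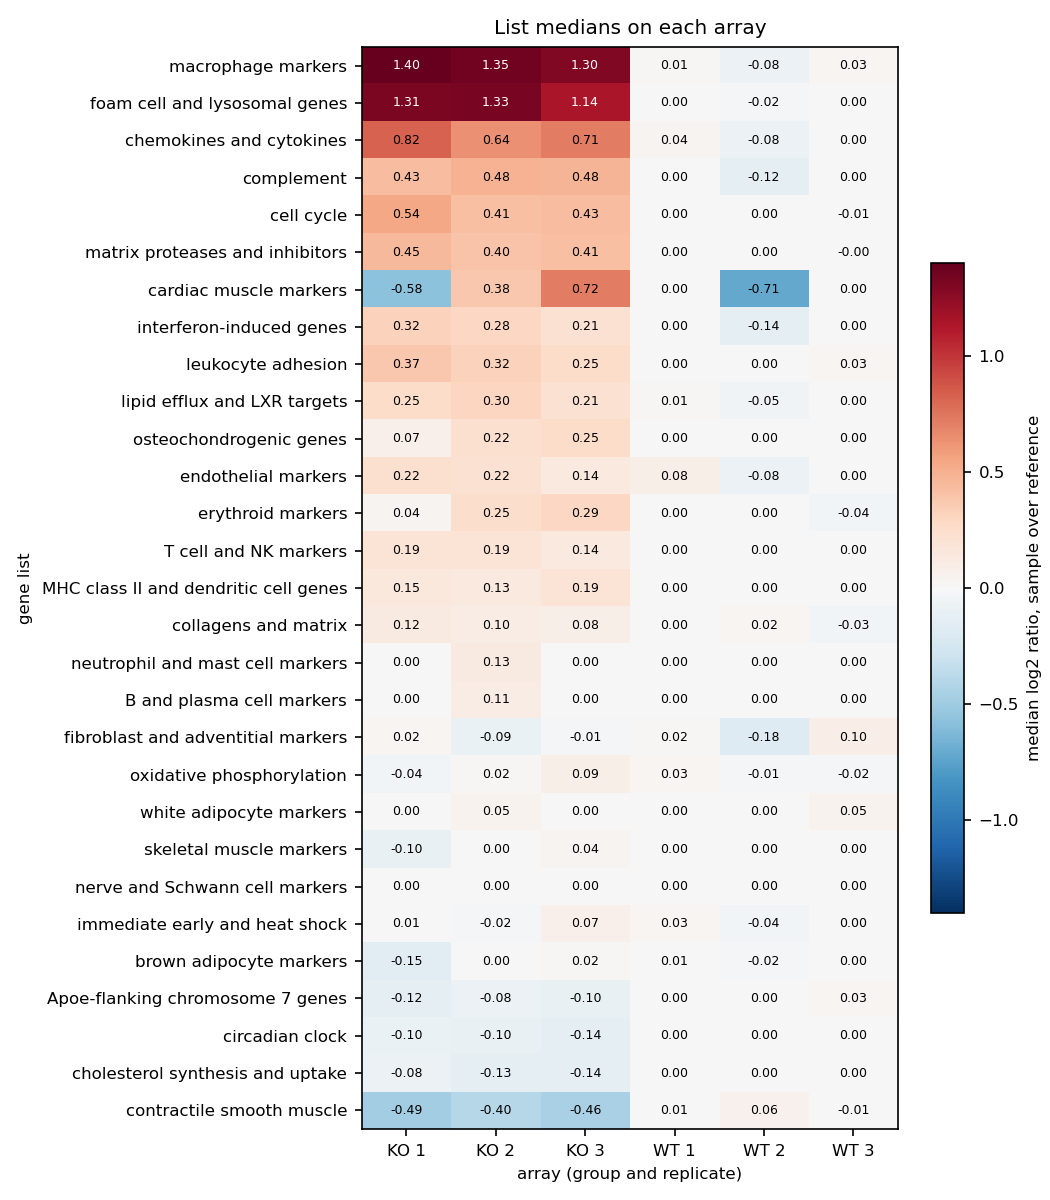
Median log2 ratio of own RNA over the common reference for each gene list (rows) on each of the 6 arrays (columns), in colour and as numbers. The 3 ApoE KO arrays lay between 1.30 and 1.40 for macrophage markers, whereas cardiac muscle markers ran from -0.58 to 0.72 within the same group.

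Genes that flank Apoe on its chromosome, a list fixed because targeted alleles carry DNA around the altered gene, fell in 11 of 41 members and rose in 3 (13 and 3 adjusted over the list alone). Bcam (-1.24), Six5 (-0.37 ± 0.022) and Clasrp (-0.35 ± 0.018) had the lowest p values, and Bcl3 (1.37), Apoc2 (0.29) and Clptm1 (0.10) were the members that rose. The calls of Apoc2 and Clptm1 were lost after quantile normalization (adjusted p 0.174 and 0.0974) and without 4 and 5 of the 6 arrays in turn (up to 0.0989 and 0.0768), that of Clptm1 also with the mean of a gene's probes (0.436) and at a level of at least 0.5 (0.0609). The median was -0.10, with an adjusted p of 0.0108 under the preset correlation and 0.414 with an estimated correlation. The call was lost without WT replicate 3 (adjusted p 0.0534) and on features with a level of at least 0.5 (0.0512). Without the measured genes nearest to Apoe, the list had a median of -0.128 and an adjusted camera p of 0.000492 under the preset correlation. Of the 10 lowest genes in the comparison, 6 lay on Apoe's chromosome, Apoe included: Bcam, Mrps12, Vmn2r29, Zfp74 and Zfp111 were the others.

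**Figure D4:**
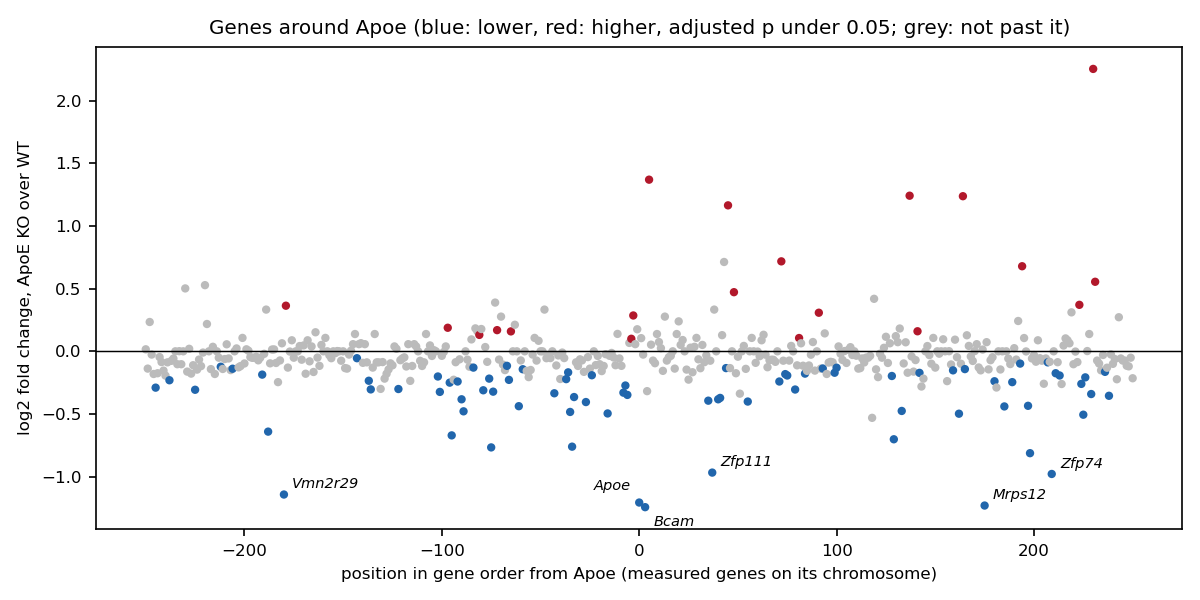
Log2 fold change of ApoE KO over WT (vertical axis) by position in gene order from Apoe among measured genes of its chromosome (horizontal axis), in blue and red where lower and higher calls passed the test and in grey elsewhere. Bcam, at 3 places from Apoe, had a log2 fold change of -1.24.

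Of the 29 lists, 22 were called with the preset correlation, 19 higher and 3 lower. With an estimated correlation 0 were called, the lowest adjusted p being 0.097, while 9 had an unadjusted p under 0.05, and the fry test, which asks whether the members of a list move 1 way on balance, called 21. At a level of at least 0.5, 14 were called, and T cell, B cell, neutrophil and erythroid markers then had fewer than 5 measured members and were not tested.

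The wild type arrays were also set against the common reference. Of 35027 features 1 differed in limma at an adjusted p under 0.05, a probe without a gene symbol that was lower by a log2 ratio of -0.13, and 488 had an unadjusted p under 0.05. Without WT replicate 1, 2 or 3 the count was 55, 35 or 75. Whether RNA of these wild type aortas is part of the reference is not given in the sources used here, and if it is, the count is no independent measure of background. The variance of the mean WT log2 ratio over features with a level of at least 0.5 was 0.628 times that of a mean of independent arrays. A reference independent of these aortas would be shared by the WT arrays and would tend to raise this ratio above 1. The value gives no sign of such a reference, although its spread was not measured. The probes at least 2-fold from the reference numbered 1, 12 and 3 in the WT arrays and 426, 383 and 383 in the ApoE KO arrays. Over features with a level of at least 0.5, the log2 ratios of ApoE KO arrays correlated across genes with r between 0.949 and 0.96, and those of WT arrays with r between -0.254 and 0.165. ApoE KO replicates 2 and 3 correlated with WT replicate 2 at r = -0.338 and -0.322 over these features, and at -0.178 and -0.163 over all features. Genes are not independent replicates in these correlations. Since the reference is described as RNA of C57BL6 controls, the low r between WT arrays does not measure how well those arrays repeat.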

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

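The fit on features with a level of at least 0.5 and the lists without neighbours of Apoe or without macrophage, foam cell and MHC class II members were chosen after seeing the data, and the other alternatives here were planned. The 5158 changed genes became 2582 with the replicate number as a block (1281 higher, 1301 lower), 1651 after quantile normalization between arrays (871 and 780), 373 with a 2-fold minimum (369 and 4) and 976 at an unadjusted p under 0.01 with 1.5-fold (823 and 153). Leaving out 1 array gave 3516 to 4901 genes in all, and between 1798 (without WT replicate 2) and 2826 lower ones, 1803 without ApoE KO replicate 3. The share of calls that were higher was 45.7%, and it ranged from 40.9 to 53.7% over the alternatives that kept an adjusted p under 0.05 with no fold minimum. With the block the oxidative phosphorylation list lost its call (adjusted p 0.0932). Called lists numbered 14 at a level of at least 0.5 and 0 with an estimated correlation, against 22. Apoe was at -1.21 with the block at an adjusted p of 0.0681, and between 0.00372 and 0.041 under its other alternatives. WT against the reference gave 35 to 75 features without 1 WT array and 6 at a level of at least 0.5, against 1. The replicate numbers share only a number: deviations of same-numbered arrays from their group means correlated at 0.078, -0.469 and -0.145 across genes, and no array correlated best with its own number. Among single named genes, 1639 of the alternative values kept their side of the threshold, 347 lost a call and 12 gained one, and among lists 434, 49 and 4. Of 146 genes, 64 lost a call under at least 1 alternative. No limma or camera test changed direction on a called result, but Lck, not called at 0.03, ranged from -0.053, where it was called, without ApoE KO replicate 2 to 0.07 without ApoE KO replicate 1, and the median of oxidative phosphorylation genes (0.01) was -0.01 without ApoE KO replicate 3. Of the 20 highest and lowest genes, Zfp74 and Zfp111 lost the call with the block (adjusted p 0.071 and 0.0634), and Zfp111 also after quantile normalization (0.11) and without ApoE KO replicate 1 (0.0505) or 3 (0.053). For each of these the cause was not tested. The other table as the source of values was not run, since its headings do not name the ApoE KO samples, nor was an average of identical arrays, since no 2 arrays were identical. Trend and robust eBayes does not apply to camera. Signal over background limits the dim features: 2364 calls had a level under 0.5, 438 of them under 0.1.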

Other observations

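All tests of explanations in this part other than the counts of splits were chosen after the results were seen. The Fisher and permutation tests take genes as independent, so their p values do not measure the spread between aortas. Grouped by the stem of the symbol, 9 of 276 families with at least 10 members held more calls than the background at an adjusted p under 0.05 in one-sided Fisher's exact tests, adjusted over 552 tests. Higher calls were more frequent in the Cd antigens (31 of 98), chemokines of the Cxcl (7 of 13) and Ccl (8 of 21) groups, interleukins and their receptors under the stem Il (19 of 82), and beta tubulins (Tubb, 6 of 10), against 10.1% of background genes. Lower calls, at 10.1% of background genes, were more frequent in the zinc finger genes (Zfp, 59 of 347) and the Arhgef exchange factors (10 of 25). They were also more frequent in the protocadherins Pcdha (7 of 12) and Pcdhga (6 of 11), which share exons. Of all features, 30.9% were called at a level of at least 0.5 and 3.3% at a level under 0.1. The tests did not match families to the background by level, so the levels of a family may contribute to its share. After quantile normalization the family medians kept their sign, but fewer members were called in each of the 9 families, down to 11 of 347 for Zfp, 2 of 13 for Cxcl and 0 of 12 for Pcdha, and with centring 1 of 11 was called for Pcdhga.

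Other splits of the 6 arrays were counted for both main results. The real grouping gave 5158 genes, and the highest of the other 9 splits gave 139, while at a level of at least 0.5 it gave 3924 and the others 0. It gave 22 lists, and the highest of the others gave 16. In each case 1 of 10 splits, the real one, was as large, and 10 splits are too few for a share under 0.05. Each other split put arrays of both genotypes on both sides, so a difference between genotypes widened its spread. Its counts therefore do not show what a grouping without any difference would give.

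Of the 10 lowest genes, 6 lay on Apoe's chromosome, Apoe included, and of the 30 lowest, 8, where the chromosome holds 8.7% of the placed genes. Within 100 measured neighbours on either side of Apoe, which takes in Bcam and Zfp111 but not Mrps12, Vmn2r29 and Zfp74 (175, -180 and 209 places from Apoe), 41 of 200 genes were called lower (20.5%, 95% Wilson interval 15.5 to 26.6), against 11.3% on the rest of the chromosome and 9.5% on other chromosomes (odds ratio against the latter 2.46, exact p = 2.64e-06, 1.58e-05 adjusted over 6 tests). For higher calls the odds ratio was 0.59 (exact p = 0.0909, 0.109 adjusted). Of the 200 genes, 5 fell by at least 1.5-fold (odds ratio 4.55, adjusted exact p 0.0125). At a level of at least 0.5 the share of lower calls was 36.2% against 16.8% on other chromosomes. The adjusted exact p was then 0.00039 for lower calls, 0.109 for falls of at least 1.5-fold and 0.409 for higher calls. These shares were not computed under other scalings. The list of flanking genes lay lower without the measured genes nearest to Apoe, at a median of -0.128 against -0.095. Its fall therefore did not rest on the genes next to Apoe. Of 93 windows of 200 genes on other chromosomes, 0 had as high a share and the highest had 16.5%, which argues against neighbours falling together as they do elsewhere, and without Zfp genes the share near Apoe was 19.0% against 9.4%. DNA of the embryonic stem cell strain kept around the targeted gene is a candidate explanation for the genes within that distance, as a hypothesis, through expression or through mismatched probes, which these data do not separate, while a smaller share of smooth muscle, genotype, age, diet length and vehicle remain open.

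Contractile smooth muscle genes fell with a median of -0.42, which incoming cells might bring about by dilution. Dilution of all resident cells would lower endothelial and fibroblast markers alike, but their medians lay above that of smooth muscle by 0.636 (two-sided permutation test with 100000 resamples, p = 2e-05, the smallest they can give) and 0.442 (permutation p = 0.00082). These p values come from permuting genes and do not measure the spread between aortas. By array, the smooth muscle median log2 ratio was -0.486, -0.397 and -0.455 in ApoE KO replicates 1, 2 and 3. It was 0.22, 0.218 and 0.137 for endothelial and 0.022, -0.092 and -0.015 for fibroblast markers. On the WT arrays the medians of these lists lay between -0.183 and 0.097. These values argue against dilution as the whole cause. A smaller share of smooth muscle alone, less of each transcript per cell, genotype, age, diet length and vehicle all remain open.

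The cardiac muscle genes Myl3 and Csrp3 were at log2 ratios of -0.90 and -0.65 in ApoE KO replicate 1, 0.30 and 0.54 in replicate 2 and 0.70 and 0.83 in replicate 3, and at -1.24 and -1.25 in WT replicate 2.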
